A study of Mus musculus with 15 samples.

How the data were processed

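RNA immunoprecipitation followed by sequencing (RIP-seq) was applied to ST2 cells, a mouse stromal cell line derived from bone marrow. Per the labels, cells were kept in medium or treated with IL-17 at 200 ng/mL for 3 h, fixed with 1% formaldehyde and lysed. Lysates were precipitated with an antibody against Arid5a, an RNA-binding protein, or with mouse IgG2b as the control. The recovered RNA was treated with DNase I and proteinase K, and stranded libraries were made from it with the SMART-Seq Stranded kit. The 15 libraries form 4 groups: IgG in medium (4), Arid5a in medium (4), IgG with IL-17 (3, numbered 2, 3 and 4) and Arid5a with IL-17 (4). No library made from unprecipitated RNA is among them.

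The authors deposited expected counts for 25239 genes in each library and FPKM (fragments scaled to gene length and to the mapped total) for the same genes. Per the labels, STAR 2.7.9, RSEM 1.3.1, DESeq2 1.36.0 and R 4.3.0 were used with the mm10 build; the role of each tool, the annotation and the strand setting are not given. The deposited expected counts were read as unnormalised RSEM estimates, since 2.66% to 10.3% of the values in a library were not whole and the totals differed between libraries. Totals ran from 939139 to 5713913 counts, and 1492 genes had 0 in all libraries. Of the gene symbols, 25041 (99.22%) matched a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, from which the coordinates were taken. That table has no strand column, and 44 of the 117 genes considered for naming overlap another gene model in it, so that reads of a neighbour could be counted for them.

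Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by group (17835) were scaled with TMM factors and fitted with robust quasi-likelihood models to the 4 group means over all 15 libraries. Genes with a Benjamini-Hochberg adjusted p below 0.05 within a comparison are called higher or lower, and every p or adjusted p of a single gene comes from this edgeR test unless another tool is named. The common biological coefficient of variation was 0.341. Values per group are TMM-scaled CPM (counts scaled to the library total) as mean ± SD, and log2 folds carry the standard error (SE) of the fit. The 5 comparisons were Arid5a against IgG in medium, Arid5a against IgG with IL-17, the difference between these (the interaction of antibody and treatment), IL-17 against medium within the Arid5a RIP, and IL-17 against medium within the IgG RIP. Overlaps of called genes were tested with a one-sided Fisher exact test.

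The comparisons, tests, 21 gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Lists were tested with limma 3.58.1 camera on voom values with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. Lists called by the preset correlation are given with the adjusted p that an estimated correlation leaves. The list of mitochondrially encoded RNAs had 0 members in the table, so it gave no test, and the alternative of leaving such genes out was void. Named genes were, for each comparison, the 10 with the largest higher and the 5 with the largest lower log2 fold among called genes with an average log2 CPM of at least 2, non-overlapping groups (not asked of the interaction) and a symbol other than Gm or Rik. To these were added up to 4 called members of each list by smallest p, and, whatever their result, Arid5a, Il6, Nfkbiz, Stat3, Cebpb, Cebpd, Cxcl1, Cxcl5, Lcn2, Zc3h12a, Tbx21, Tnfrsf4, Gapdh, Actb and Malat1. Genes named outside this rule are stated to have been chosen after their values were seen.

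Alternatives were upper-quartile factors, library totals without factors, DESeq2 1.42.0 with its own size factors, limma voom with sample quality weights, no filter and a stricter filter (at least 10 counts in every library of a group), only the libraries compared, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and each library left out in turn. Added after seeing the data were TMM factors from the 5213 genes with an average log2 CPM of at least 5 (called well-expressed below), the CPM on olfactory and vomeronasal receptor genes as a covariate, the joint removal of IgG medium 2 and IgG IL-17 4 (the libraries farthest from the rest of their groups), the joint removal of Arid5a IL-17 1, 2 and 3, Arid5a libraries thinned to the total of the shallowest, and, for ribosomal protein mRNAs in medium, library totals with an estimated correlation.

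The procedure was tested on simulated counts with the group sizes of the study, in which 100 genes changed 2-fold and 100 changed 4-fold. For Arid5a against IgG in medium, edgeR recovered 20 of the 2-fold and 66 of the 4-fold genes and called 4 unchanged genes of 17174 tested. For IL-17 against medium within the Arid5a RIP it recovered 28 and 61 and called 5 unchanged genes of 17193 tested, and for the interaction it recovered 11 and 36. No changed gene was called with the wrong sign in these comparisons. Apart from the changed genes, as many raised as lowered, the simulated groups had the same profile. The simulation therefore does not cover a shift of the scaling between groups. A value of 0 in a library allows up to 3 counts, which corresponds to 0.525 CPM in the deepest and 3.19 CPM in the shallowest library; such floors cover counting error only. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples.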

Results

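The study asked which transcripts are bound by Arid5a, an AT-rich interaction domain protein known to bind and stabilise mRNAs of inflammatory genes, in stromal cells responding to IL-17. RNA co-precipitated with an Arid5a antibody or with mouse IgG2b was sequenced from ST2 cells in medium or after IL-17. IgG medium libraries 1 to 4 held 4580018, 939139, 3048529 and 3038327 counts. Arid5a medium libraries 1 to 4 held 2952937, 2128688, 2914456 and 3636336. IgG IL-17 libraries 2 to 4 held 4496924, 2775608 and 2216655. Arid5a IL-17 libraries 1 to 4 held 5426819, 4954465, 5713913 and 3411753. Within groups, log2 CPM of library pairs correlated across genes with a Pearson r between 0.818 and 0.968.

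Counts on 1470 olfactory and vomeronasal receptor genes, which are silent in most cells outside the sensory epithelia, were compared between groups. They made up 2224 ± 613 CPM (SD, n = 4) in IgG medium and 4178 ± 964 (n = 4) in Arid5a medium. With IL-17 they made up 2979 ± 685 (n = 3) in IgG IL-17 and 2114 ± 1363 (n = 4) in Arid5a IL-17 libraries. In the last group, replicate 4 held 4149 CPM and replicates 1 to 3 held 1456, 1581 and 1269. Arid5a medium exceeded IgG medium by 1954 CPM (two-sided exact permutation p = 0.0286, adjusted over the 4 comparisons of this measure 0.114). With IL-17 the Arid5a libraries were below the IgG libraries by a mean difference of -865 CPM, with an exact permutation p of 0.314.

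**Figure D1:**
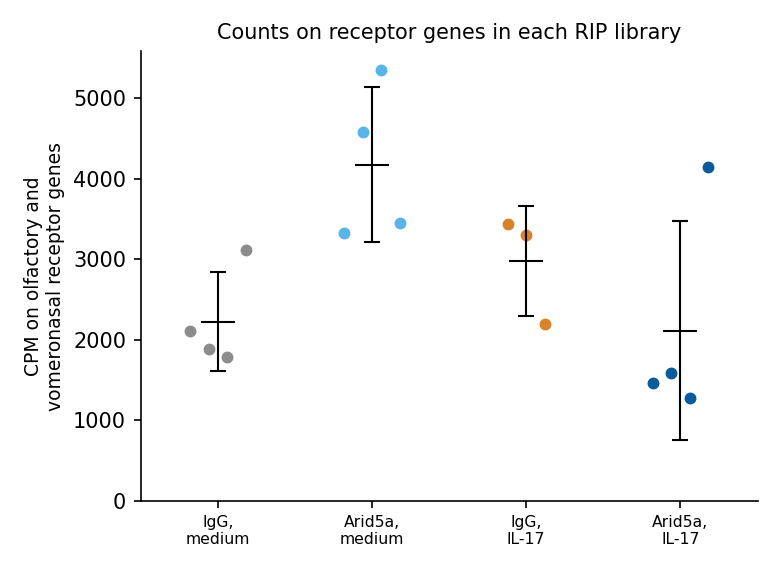
CPM (unscaled, of all counts) on olfactory and vomeronasal receptor genes (y axis) in each library (points), by group (x axis), with the group mean and SD as bars. Arid5a medium libraries held 4178 ± 964 CPM and IgG medium libraries 2224 ± 613 CPM. Replicate 4 of Arid5a IL-17 stood at 4149 CPM, above the other replicates of its group.

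The comparison of Arid5a with IgG in medium asked which transcripts the antibody enriched before stimulation, and few were higher. Nsa2, a ribosome biogenesis factor, stood at 358 ± 56.6 CPM (SD, n = 4) in the Arid5a RIP and 219 ± 36.3 CPM (n = 4) in the IgG RIP, a log2 fold of 0.71 ± 0.16 (SE, adjusted p = 0.0279). The histone gene H4c4 was higher by 0.66 ± 0.16 (adjusted p = 0.0464). So were the small Cajal body RNA Scarna13 by 2.24 ± 0.42 (adjusted p = 0.0459) and Kcnj3, a potassium channel subunit, by 2.24 ± 0.56 (adjusted p = 0.0470). Kcnj3 was low, with 1 to 18 counts in IgG medium and 28 to 54 in Arid5a medium libraries. Scarna13 lies within the model of its host gene Snhg10, and Nsa2 (chromosome 13, 97129427 to 97137926, mm10) overlaps Fam169a. Of 17835 transcripts tested with edgeR, 10 were higher and 102 lower in the Arid5a RIP, and 2279 had an unadjusted p below 0.05.

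Of the lower transcripts in medium that the naming rule allows, the largest folds were those of Churc1 (log2 fold -1.52 ± 0.34), Pdrg1 (-1.38 ± 0.26), the activin-binding protein gene Fstl3 (-1.22 ± 0.28), Mfsd14a (-1.16 ± 0.25) and Cdk7 (-1.10 ± 0.20), a kinase of the transcription factor TFIIH. Their adjusted p lay between 0.0148 and 0.0348. The chemokine genes Ccl7 (-0.94 ± 0.19, adjusted p = 0.0171) and Ccl9 (-0.67 ± 0.17, adjusted p = 0.0483) were lower too. Among lists, 3 of 31 proteasome subunits were lower (Psma1, Psmd1 and Psmd6; 8 when adjusted over the list alone). So were 2 of 34 cell cycle genes (Rrm2 and Birc5; 7 lower and 1 higher when adjusted over the list alone). Also lower were 2 of 25 housekeeping mRNAs (Ywhaz and Ppia; 5 adjusted over the list alone) and 2 of 46 mRNA decay and stability factors (Zfp36l2 and Celf1; 7 adjusted over the list alone). Of 35 extracellular matrix genes, Col1a1 was lower (-0.48 ± 0.12; 1 adjusted over the list alone). Among the 36 immediate early and C/EBP factors, Ier5 alone was lower over all genes (2 adjusted over the list alone). Among 26 noncoding RNAs Malat1 was lower (-0.47 ± 0.12; 3 adjusted over the list alone). The medians of the housekeeping, mRNA decay, matrix, immediate early and noncoding lists, all below 0, turned above 0 with factors from well-expressed genes (0.05, 0.08, 0.01, 0.02 and 0.15). By camera 9 of 20 lists shifted lower, and an estimated correlation ended all of these calls (adjusted p from 0.193 to 0.397). With the preset correlation, adjusted p were 3.13e-10 for cell cycle genes, 1.51e-07 for proteasome subunits, 2.99e-06 for matrix genes, 0.000234 for mRNA decay factors and 0.000474 for housekeeping mRNAs. They were 0.00460 for IL-17 receptor signalling, 0.00487 for IL-17-inducible genes, 0.00721 for stromal genes and 0.0107 for immediate early and C/EBP factors. With factors from well-expressed genes the proteasome median moved from -0.30 to -0.12, that of cell cycle genes from -0.25 to -0.07 and that of IL-17-inducible genes from -0.46 to -0.27. The medians of IL-17 receptor signalling and of stromal genes moved from -0.19 to -0.01 and from -0.20 to -0.02. Predicted Gm genes shifted higher (adjusted p = 7.82e-08, median log2 fold 0.50, adjusted p = 0.243 with an estimated correlation), with 3 of 689 called over all genes and 1 adjusted over the list alone.

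None of the 6 measured transcripts reported to bind Arid5a was called in medium by edgeR, DESeq2 or voom. By edgeR 1 had an unadjusted p below 0.05 (Cebpb, -0.59 ± 0.20, the only member lower when adjusted over the list alone). Stat3 stood at -0.23 ± 0.20, Nfkbiz at -0.16 ± 0.21, Cxcl1 at -0.55 ± 0.32, Cxcl5 at -0.12 ± 0.59 and Tbx21 at 1.17 ± 0.58. The transcript of Arid5a itself was at -0.07 ± 0.37 (15.4 ± 4.10 CPM against 15.7 ± 6.11 CPM). Gapdh was at 0.23 ± 0.13, Actb at -0.13 ± 0.12, Cebpd at -0.28 ± 0.28 and Zc3h12a at -0.86 ± 0.28 (adjusted p = 0.155). Il6, Lcn2 and Tnfrsf4 had at most 8, 7 and 12 counts in any library and did not pass the filter. They were not tested in the main fit, and at such counts only a large difference could be seen.

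The 112 calls in medium depended on scaling and on single libraries. TMM left the 5213 well-expressed genes at a median of -0.19 (log2). The split of 10 higher and 102 lower became 2 and 2 with upper-quartile factors, 8 and 5 with library totals and 7 and 3 with factors from well-expressed genes. It was 26 and 301 with DESeq2. Only Nsa2 and H4c4 (higher) and Esd and Tacc3 (lower; these last were chosen after their values were seen) were called under all 5 scalings. Leaving out a library gave from 0 calls (IgG medium 3, Arid5a medium 2 or Arid5a medium 3, with 1944, 1562 and 1504 at an unadjusted p below 0.05 by edgeR) to 350 (IgG medium 1), with 2 without IgG medium 2.

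After IL-17, the transcripts higher in the Arid5a RIP than in the IgG RIP again included Nsa2, at 461 ± 117 CPM (n = 4) against 221 ± 1.38 CPM (n = 3), a log2 fold of 1.06 ± 0.17 (adjusted p = 0.00697). Close to it were Rwdd1 (1.06 ± 0.18), the S-adenosylmethionine synthase gene Mat2a (1.02 ± 0.18) and Cyb5r3, a reductase of cytochrome b5 (1.02 ± 0.17). Further ones were Ap3s1, a subunit of the AP-3 adaptor (1.04 ± 0.22), and Hbs1l, a ribosome rescue factor (0.88 ± 0.17). Ppp1r11 (0.95 ± 0.20), the kinesin gene Kif1c (0.75 ± 0.15) and Sh3glb1 (0.71 ± 0.15) were the others. Adjusted p of these 8 lay between 0.00708 and 0.0491. Gm32687 was at 0 in all IgG IL-17 libraries and at 8.21 ± 2.34 CPM in Arid5a IL-17, at least 7.87-fold higher against a floor of 3 counts per library. The small nucleolar RNA Snord1b, within the model of Snhg16, was lower (-2.13 ± 0.44, adjusted p = 0.0491). Zfp433, at 0 in all Arid5a IL-17 libraries and 6.93 ± 2.04 CPM in IgG IL-17, was at least 10.1-fold higher in the IgG RIP. It was also at 0 in all IgG medium libraries and had at most 2 counts in an Arid5a medium library. Gm32687 was at 0 throughout a group only in IgG IL-17, so both folds rest on the IgG IL-17 libraries. Both genes lie on chromosome 10, starting at 81704747 and 81863769. Of 17835 transcripts, edgeR called 10 higher and 2 lower, and 1596 had an unadjusted p below 0.05.

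With IL-17 none of the 6 reported Arid5a-bound transcripts was called by edgeR, with 2 at an unadjusted p below 0.05. DESeq2 called 1 lower, and voom 1 higher and 1 lower. Cxcl5 stood at 0.69 ± 0.29, Cxcl1 at -0.08 ± 0.24, Nfkbiz at 0.30 ± 0.20, Stat3 at 0.19 ± 0.20, Cebpb at -0.02 ± 0.21 and Tbx21 at -1.92 ± 0.61. Zc3h12a was at 0.18 ± 0.25, Cebpd at -0.01 ± 0.26, Arid5a at -0.17 ± 0.38, Malat1 at 0.39 ± 0.13, Actb at 0.39 ± 0.13 and Gapdh at 0.04 ± 0.14, none of them called. By camera 7 lists shifted higher, each with an adjusted p of 0.383 under an estimated correlation. They were ribosomal protein mRNAs (81 measured, adjusted p = 3.10e-10), housekeeping mRNAs (25, 3.41e-10), mRNA decay factors and matrix genes (0.000153 for both), cell cycle and histone genes (0.00106 for both) and proteasome subunits (0.0472). Their medians, between 0.10 and 0.24, lay between -0.05 and 0.08 with factors from well-expressed genes. Arid5a IL-17 4 lay below IgG IL-17 over matrix genes (37570 CPM against 41410 to 42310) and cell cycle genes (5604 against 6094 to 6226). Over housekeeping mRNAs it lay within IgG IL-17 (40290 against 39180 to 40880). Over ribosomal protein mRNAs it lay above (59600 against 48580 to 56940). No ribosomal protein or housekeeping mRNA was called by edgeR over all genes, while 14 and 4 were higher when adjusted over the list alone. An unadjusted p below 0.05 was found for 23 and 8, DESeq2 called 2 and 1, and voom called 15 and 5. Epithelial and endothelial cell markers (20 measured, median -0.88) shifted lower (adjusted p = 0.000679; 0.383 with an estimated correlation), as did predicted Gm genes (689 measured, median -0.35, adjusted p = 7.32e-05; 0.383 with an estimated correlation). Replicate 4 of Arid5a IL-17 shared neither shift. Summed over the marker list it held 95.9 CPM against 88.6 to 99.7 in IgG IL-17, and over the Gm genes 8167 against 6114 to 7849. Replicates 1 to 3 held 27.7 to 48.5 and 4807 to 5396.

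The 12 calls with IL-17 became 6 with upper-quartile factors, 60 with DESeq2 (35 higher and 25 lower) and 571 with voom (271 higher and 300 lower). They became 0 with factors from well-expressed genes (1439 at an unadjusted p below 0.05), where TMM had left the median of these genes at 0.15. Without Arid5a IL-17 4 there were 76 calls and without IgG IL-17 4 there were 2. Nsa2 was called with each of the 15 libraries left out but had an adjusted p of 0.0722 with factors from well-expressed genes, at a log2 fold of 0.93 ± 0.18.

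Nsa2 was the only transcript called higher in the Arid5a RIP in both conditions, against 0.00561 expected for independent sets of 10 and 10 (one-sided Fisher exact p = 0.00559). The overlap was 0 in 11 of 29 other fits, among them each of the 4 fits that left out 1 Arid5a medium library. Across all 17835 genes, which are not independent replicates, the log2 folds of the RIP in medium and with IL-17 had a Pearson r of -0.21, and across the 5213 well-expressed genes -0.05.

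The difference of Arid5a enrichment between IL-17 and medium asked which transcripts gained or lost in the Arid5a RIP beyond the change in the IgG RIP. Ccl7 (chromosome 11, 82045712 to 82047525), a monocyte chemokine and IL-17 target, was among the gains with the smallest adjusted p, at 1.53 ± 0.26 (adjusted p = 0.0148). It was at 33.2 ± 2.11 CPM in the Arid5a and 65.6 ± 18.8 CPM in the IgG RIP in medium (n = 4 and 4). With IL-17 it was at 240 ± 33.1 and 160 ± 13.7 CPM (n = 4 and 3). Larger gains were those of Alg8, a glucosyltransferase of N-glycosylation (2.65 ± 0.69), Zmynd19 (2.23 ± 0.45) and the centromere protein gene Cenpm (1.89 ± 0.49). Also larger were those of the oligosaccharyltransferase genes Rpn1 (1.76 ± 0.32) and Ostc (1.56 ± 0.31), the proteasome assembly factor gene Psmg4 (1.67 ± 0.35), Pdrg1, Pithd1, Mfsd14a and Prr13. Among the genes that the naming rule allows, losses were largest for the olfactory receptor gene Olfr1385 (-3.79 ± 0.94), the orphan receptor gene Gpr101 (-3.57 ± 0.92), Pcdhga9 (-2.94 ± 0.72), Ugt1a1 (-2.31 ± 0.46) and the cadherin gene Cdh4 (-2.30 ± 0.59). Of these, Pcdhga9 and Ugt1a1 lie in gene clusters with shared exons. Counts per library were low for Olfr1385 (1 to 7 in IgG medium and 4 to 17 in Arid5a IL-17) and Gpr101 (1 to 9 and 8 to 18). In Gpr101, replicate 4 of Arid5a IL-17 stood above its group (5.10 CPM, others 1.68 to 2.11), as it did in receptor-gene CPM. Whether the losses follow the counts on silent genes was not tested. In the TMM fit, each of the larger gains named joined a rise with IL-17 in the Arid5a RIP to a fall in the IgG RIP. These were 1.09 and -1.56 for Alg8, but 0.21 and -1.68 for Cenpm and 0.32 and -1.32 for Mfsd14a. The rise of Cenpm lay below, and that of Mfsd14a close to, the median of 0.31 of all well-expressed genes in the Arid5a RIP. Both gains thus rested mainly on the fall in the IgG RIP. Each of the losses named joined a fall in the Arid5a RIP to a rise in the IgG RIP, such as -0.67 and 2.26 for Pcdhga9. In all, 155 transcripts gained and 19 lost, and 2905 had an unadjusted p below 0.05. A gain need not mean enrichment with IL-17, since Ccl7, Pdrg1 and Mfsd14a were called lower in the Arid5a RIP in medium. Mfsd14a was at 57.82 and 25.09 CPM in IgG and Arid5a medium, and at 22.46 and 31.25 CPM with IL-17. Only 10 transcripts were called higher in the Arid5a than in the IgG RIP with IL-17.

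By list, 3 of 25 housekeeping mRNAs gained (Ywhaz, Ppia and Hprt, and 8 adjusted over the list alone). So did 2 of 31 proteasome subunits (Psmd6 and Psmd1, and 8 adjusted over the list alone) and 1 of 81 ribosomal protein mRNAs (Rpl35, and 8 adjusted over the list alone). Gains were also called for 2 of 22 cytokines and chemokines (Ccl7 and Ccl9; 5 gained and 2 lost adjusted over the list alone) and 1 of 18 IL-17-inducible genes (Ccl7; 4 adjusted over the list alone). Among nuclear and housekeeping noncoding RNAs, Malat1 (0.86 ± 0.17) and Neat1 (0.77 ± 0.18) gained and Meg3 lost (-1.60 ± 0.41), with 3 and 1 adjusted over the list alone. The medians of the proteasome, ribosomal and noncoding lists, above 0 in the TMM fit, turned below 0 with factors from well-expressed genes (-0.04, -0.13 and -0.31). None of the 6 reported Arid5a-bound transcripts was called by edgeR, with 1 at an unadjusted p below 0.05 and 1 lost when adjusted over the list alone (Tbx21, -3.08 ± 0.84, adjusted p = 0.0601). Of these 6, DESeq2 called 1 lost, and voom 1 gained and 1 lost. Tbx21 was low, at 3.27 ± 2.29 and 8.23 ± 0.969 CPM in IgG and Arid5a medium, and at 9.42 ± 1.98 and 2.47 ± 1.01 CPM with IL-17. Its counts ran from 0 to 24 in IgG medium and from 7 to 20 in Arid5a IL-17 libraries. Camera placed 9 lists higher, and an estimated correlation ended each call (adjusted p from 0.208 to 0.217). Adjusted p were 6.16e-09 for housekeeping mRNAs and for cell cycle genes, 1.78e-07 for matrix genes, 3.98e-07 for ribosomal protein mRNAs, 3.32e-06 for mRNA decay factors and 5.68e-06 for proteasome subunits. They were 0.00702 for immediate early and C/EBP factors, 0.00750 for IL-17 receptor signalling and 0.00836 for IL-17-inducible genes. With factors from well-expressed genes the median of IL-17-inducible genes moved from 0.52 to 0.18, that of housekeeping mRNAs from 0.39 to 0.04 and that of cell cycle genes from 0.43 to 0.07. The medians of IL-17 receptor signalling, immediate early, mRNA decay and matrix genes, all above 0 in the TMM fit, turned below 0 (-0.06, -0.08, -0.05 and -0.01). Arid5a IL-17 4 lay below replicates 1 to 3 over matrix genes (37570 CPM against 43470 to 45770), cell cycle genes (5604 against 6179 to 6623) and housekeeping mRNAs (40290 against 42450 to 47610). Over ribosomal protein mRNAs it lay within their range (59600 against 54100 to 59860). Epithelial and endothelial cell markers were shifted lower (adjusted p = 0.00836, median -0.96, adjusted p = 0.208 with an estimated correlation), which replicate 4 of Arid5a IL-17 did not share (95.9 CPM summed over the list, against 27.7 to 48.5 in replicates 1 to 3). Predicted Gm genes were shifted lower (adjusted p = 6.16e-09, median -0.87, adjusted p = 0.208 with an estimated correlation), with replicate 4 of Arid5a IL-17 at 8167 CPM over the list and replicates 1 to 3 at 4807 to 5396. Interferon response genes had a median of -0.40 (adjusted p = 0.0673).

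These 174 calls ended under other scalings. Upper-quartile factors, library totals and factors from well-expressed genes each gave 0 calls (2446, 2527 and 2594 at an unadjusted p below 0.05 by edgeR). TMM had left the median of well-expressed genes at 0.35. Across these scalings the median difference of the 155 gains went from 1.09 to 0.82, 0.78 and 0.73, and that of the 19 losses from -4.32 to -4.55, -4.60 and -4.64. That they kept their direction does not weigh the scaling. The transcripts were chosen for large differences in the TMM fit, and removing a shared shift of 0.35 could hardly reverse them. DESeq2 gave 394 (226 higher and 168 lower) and voom 1758 (938 higher and 820 lower). Leaving out a library gave from 0 (Arid5a IL-17 1, with 2239 at an unadjusted p below 0.05) to 715 (Arid5a IL-17 4).

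Within the Arid5a RIP, IL-17 raised chemokine and inflammatory transcripts. Cxcl5, a neutrophil chemokine, went from 1.11 ± 0.127 to 75.6 ± 14.4 CPM (n = 4 and 4), a log2 fold of 6.05 ± 0.39 (adjusted p = 7.99e-14). Cxcl1 rose by 4.36 ± 0.28, and the monocyte chemokines Ccl2 by 3.17 ± 0.18 and Ccl7 by 2.85 ± 0.18. The death receptor gene Fas rose by 3.05 ± 0.28 and Zc3h12a, which encodes the mRNA-degrading endonuclease Regnase-1, by 2.79 ± 0.26. Adjusted p of these 6 lay between 5.37e-15 and 2.34e-09. Complement C3 (2.58 ± 0.58), the angiogenic factor gene Vegfa (2.14 ± 0.17), the annotated pseudogene Serpina3h (2.09 ± 0.35) and Ptgs2, the inducible prostaglandin synthase (1.98 ± 0.30), completed the 10 largest among the genes that the naming rule allows. Of 17835 transcripts, 863 were higher and 145 lower, and 3972 had an unadjusted p below 0.05.

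IL-17-inducible genes rose as a list in the Arid5a RIP, with 13 of 18 higher (14 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.39e-19, and 0.000451 with an estimated correlation). The NF-kB and IkB family had 6 of 13 higher (7 adjusted over the list alone, adjusted p = 1.32e-09, and 0.00125 with an estimated correlation). Among them were Nfkbiz (1.94 ± 0.20), the inhibitor gene Nfkbia (1.87 ± 0.22), Nfkb2 (1.41 ± 0.20) and Nfkb1 (1.12 ± 0.20). Among the reported Arid5a-bound transcripts, Cxcl5, Cxcl1, Nfkbiz, Cebpb (0.82 ± 0.20) and Stat3 (0.66 ± 0.19) rose and Tbx21 stood at -1.72 ± 0.58 (adjusted p = 0.0698). This makes 5 of 6 higher (5 higher and 1 lower adjusted over the list alone, adjusted p = 3.39e-07, and 0.00809 with an estimated correlation). Cxcl5, Cxcl1 and Nfkbiz were called under all 5 scalings, and Cebpb and Stat3 were not. Cytokines and chemokines had 7 of 22 higher (8 adjusted over the list alone, adjusted p = 0.00235, and 0.0310 with an estimated correlation). Their median was -0.20 and their mean 0.39. The IL-17 receptor signalling list had 6 of 34 higher (11 adjusted over the list alone, adjusted p = 2.43e-06, and 0.0439 with an estimated correlation), Tnfaip3 and Srsf1 among them. Its median of 0.34, close to the 0.31 of all well-expressed genes, moved to 0.09 with library totals and 0.03 with factors from well-expressed genes.

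Extracellular matrix genes had 19 of 35 higher in the Arid5a RIP with IL-17 (24 adjusted over the list alone, adjusted p = 1.25e-15, and 0.0480 with an estimated correlation). Among them were Timp3, an inhibitor of metalloproteinases (2.56-fold), tenascin Tnc (1.08 ± 0.16), fibrillin Fbn1 (0.81 ± 0.13) and the cross-linking enzyme gene Lox (0.68 ± 0.12). The list's median moved from 0.46 to 0.15 with factors from well-expressed genes. Replicate 4 of Arid5a IL-17 did not share the rise, with 37570 CPM summed over the list against 37120 to 39350 in medium and 43470 to 45770 in replicates 1 to 3. Of 46 mRNA decay and stability factors, 10 were higher (16 adjusted over the list alone, adjusted p = 1.28e-08, and 0.0650 with an estimated correlation), among them Rc3h1 (Roquin-1), Elavl1 and Pabpc1, and the median moved from 0.36 to 0.05 with the same factors. Of 81 ribosomal protein mRNAs, 21 were higher (30 higher and 1 lower adjusted over the list alone, adjusted p = 1.00e-11, and 0.101 with an estimated correlation), such as Rps26 (1.13 ± 0.16). The list's median of 0.22 turned to -0.03 with library totals and -0.09 with factors from well-expressed genes. Proteasome subunits had 7 of 31 higher (14 adjusted over the list alone, adjusted p = 2.44e-08, and 0.0538 with an estimated correlation), with a median that moved from 0.40 to 0.09. Cell cycle genes had 0 of 34 called by edgeR (9 at an unadjusted p below 0.05, 1 higher by DESeq2 and 19 by voom, 0 adjusted over the list alone by edgeR, adjusted p = 1.92e-05, and 0.180 with an estimated correlation), and their median of 0.25 turned to -0.07. Housekeeping mRNAs had 7 of 25 higher, Tpt1 and Actg1 among them (10 adjusted over the list alone, adjusted p = 3.58e-09, and 0.130 with an estimated correlation). Their median of 0.30 turned to -0.02 with factors from well-expressed genes. Tpt1 was called under all 5 scalings, while Actg1 was not and stood at -0.054 without Arid5a IL-17 1, 2 and 3. Replicate 4 again lay apart, with 40290 CPM over this list against 40770 to 47030 in medium and 42450 to 47610 in replicates 1 to 3. Over the cell cycle genes it held 5604 CPM, against 5630 to 6538 in medium and 6179 to 6623 in replicates 1 to 3. Cebpd (1.96 ± 0.26) and Klf6 (0.57 ± 0.15) were among 5 immediate early and C/EBP factors that rose of 36, while Fos fell by 1.40 ± 0.40. This list had 6 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0890), and its median of 0.14 turned to -0.19 with factors from well-expressed genes. Malat1 (0.82 ± 0.12), Neat1 (0.74 ± 0.12) and Snhg5 (1.48 ± 0.27) were among 4 of 26 noncoding RNAs that rose. Meg3 was 1 of 2 that fell (-1.22 ± 0.28; 4 and 4 adjusted over the list alone, adjusted p = 0.890). Vcam1 (1.03 ± 0.27) and the decoy receptor gene Tnfrsf11b (0.74 ± 0.15) rose and Bmp4 fell (-0.57 ± 0.18) among 30 stromal, osteoblast and adipocyte genes (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.890).

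The largest falls with IL-17 in the Arid5a RIP, by the same rule, were those of the olfactory receptor genes Olfr1342 (-2.23 ± 0.67) and Olfr406 (-2.10 ± 0.60), Ascl2 (-2.16 ± 0.65), Ddn (-2.09 ± 0.44) and Ccdc149 (-2.06 ± 0.58). Receptor-gene CPM moved by -2064 in this comparison (exact permutation p = 0.0857). Epithelial and endothelial cell markers had a median of -1.02 with no member called by edgeR (20 measured, 4 at an unadjusted p below 0.05, 0 adjusted over the list alone, 0 by DESeq2 and 11 lower by voom). Haematopoietic markers had a median of -0.99 with Cd8a lower (12 measured, 2 lower adjusted over the list alone). Their camera adjusted p were 0.000264 and 0.0281, and 0.0632 and 0.166 with an estimated correlation. Predicted Gm genes had 1 higher and 9 lower of 689 by edgeR, 2 and 33 by DESeq2 and 13 and 283 by voom (2 lower adjusted over the list alone by edgeR, median -0.76, adjusted p = 1.32e-09, and 0.130 with an estimated correlation). In these 3 lists replicate 4 of Arid5a IL-17 stood above replicates 1 to 3. Summed over the epithelial and endothelial list it held 95.9 CPM against 32.8, 27.7 and 48.5 in replicates 1 to 3. Over the haematopoietic list it held 50.7 CPM against 26.0, 19.6 and 22.1, and over the Gm genes 8167 CPM against 5161, 4807 and 5396. Zfp genes had 8 of 343 higher (4 adjusted over the list alone, camera adjusted p = 0.214), with a median of 0.06 that turned to -0.24 with factors from well-expressed genes. Replication-dependent histone genes had 4 higher and 2 lower of 60 (5 and 3 adjusted over the list alone, camera adjusted p = 0.214). Interferon response genes had 0 of 23 called by edgeR (0 at an unadjusted p below 0.05, 0 by DESeq2, 1 higher and 3 lower by voom). Arid5a stood at 0.35 ± 0.36 and Gapdh at 0.09 ± 0.13, neither called. Actb rose by 0.43 ± 0.12 over a median of 0.31 for well-expressed genes. It was not called under all 5 scalings and stood at -0.00303 without Arid5a IL-17 1, 2 and 3.

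The 1008 calls fell to 321 with upper-quartile factors (202 higher and 119 lower) and 301 with library totals (156 and 145). They fell to 324 with factors from well-expressed genes (113 and 211, of which 232 were among the 1008). DESeq2 gave 1350 (795 and 555) and voom 7497 (3372 and 4125), while receptor-gene CPM as a covariate left 27 (25 and 2). All 5 scalings called 113 higher and 93 lower, among them the 10 transcripts listed first above. Leaving out a library gave between 308 (Arid5a IL-17 2) and 2257 calls (Arid5a IL-17 4). C3, Serpina3h and Ptgs2 were not called when Arid5a IL-17 1, 2 and 3 were all left out.

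**Figure D2:**
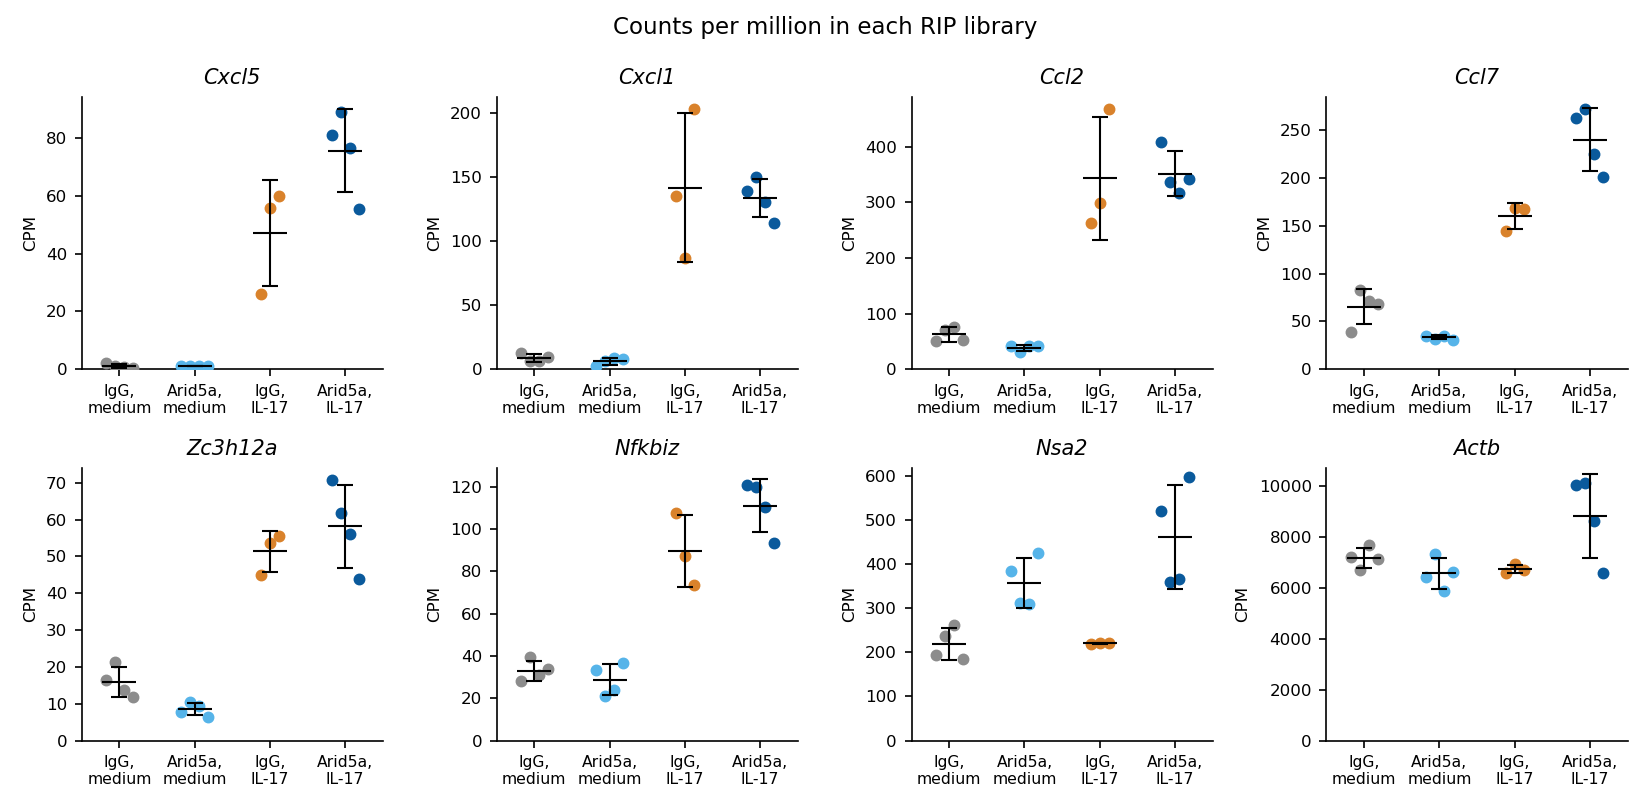
TMM-scaled CPM (y axes, linear from 0) of 8 transcripts in each library (points) by group (x axes), with the group mean and SD as bars. Cxcl5, Cxcl1, Ccl2, Ccl7, Zc3h12a and Nfkbiz were higher with IL-17 in both RIPs. Nsa2 was higher in the Arid5a than in the IgG RIP in both conditions, and Actb stood between 6578 and 8846 CPM in the group means.

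Within the IgG RIP, which served as the background of the method and carried no Arid5a antibody, IL-17 raised many of the same inflammatory transcripts. Cxcl5 went from 1.09 ± 0.812 (n = 4) to 47.2 ± 18.4 CPM (n = 3), a log2 fold of 5.24 ± 0.41 (adjusted p = 3.39e-11). Cxcl1 rose by 3.89 ± 0.28, Ccl2 by 2.47 ± 0.19, Serpina3h by 2.32 ± 0.39, Fas by 2.23 ± 0.29 and Zc3h12a by 1.75 ± 0.27 (adjusted p from 1.44e-11 to 0.000982). C3 (2.69 ± 0.65), the protease inhibitor gene Slpi (2.68 ± 0.64), Pcdhga9 (2.26 ± 0.54) and Relb (1.82 ± 0.43) rose with adjusted p from 0.0366 to 0.0414. In all, 46 transcripts were higher and 42 lower, and 1988 had an unadjusted p below 0.05.

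By list in the IgG RIP, 8 of 18 IL-17-inducible genes were higher (12 adjusted over the list alone, camera adjusted p = 4.65e-29, and 5.87e-05 with an estimated correlation). Of 6 reported Arid5a-bound transcripts, Cxcl5, Cxcl1 and Nfkbiz were higher (3, and 4 adjusted over the list alone, with an adjusted p of 2.90e-11, and 0.000928 with an estimated correlation). Of 13 NF-kB and IkB genes 3 were higher, namely Nfkbiz (1.48 ± 0.21), Nfkb1 (1.34 ± 0.22) and Relb. Adjusted over the list alone these were 7, with a camera adjusted p of 6.63e-10, and 0.000928 with an estimated correlation. Of 22 cytokines and chemokines 4 were higher, and Kitl, which encodes stem cell factor, was lower (-0.89 ± 0.19). Adjusted over the list alone, 7 were higher and 1 lower (camera adjusted p = 0.00121, and 0.0144 with an estimated correlation). The guanylate-binding protein genes Gbp2 (3.82 ± 0.78) and Gbp3 (3.57 ± 0.82) rose by edgeR among 23 interferon response genes, from at most 4 and 7 counts in any IgG medium library, but DESeq2 and voom called 0 of the list (2 adjusted over the list alone, adjusted p = 0.0366, and 0.318 with an estimated correlation). Lower were Cenpm (-1.68 ± 0.38), Mfsd14a (-1.32 ± 0.27), the growth factor gene Bmp4 (-1.18 ± 0.20), the immediate early gene Egr1 (-1.17 ± 0.18) and Trip4 (-1.15 ± 0.26). So were Fos (-1.98 ± 0.47) and Rps7 (-1.12 ± 0.23). Cell cycle genes had 2 of 34 lower (Rrm2 and Birc5), and 5 adjusted over the list alone. Their camera adjusted p was 4.25e-05, and 0.350 with an estimated correlation. Rrm2 was at 335.6 ± 91.42 CPM in IgG medium, 200.3 ± 21.29 in Arid5a medium, 194.5 ± 8.84 in IgG IL-17 and 204.1 ± 42.71 in Arid5a IL-17. The comparison in medium, the difference and this comparison share the 4 IgG medium libraries. Calls of the same gene in them are therefore not independent. Matrix genes shifted higher with 1 of 35 called (3 adjusted over the list alone, adjusted p = 0.00495, and 0.481 with an estimated correlation). Stromal genes shifted lower with 2 of 30 called (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.00596, and 0.116 with an estimated correlation). Cebpd rose by 1.70 ± 0.28, while Cebpb (0.25 ± 0.21), Stat3 (0.25 ± 0.21), Arid5a (0.45 ± 0.39), Gapdh (0.27 ± 0.14), Actb (-0.09 ± 0.13) and Malat1 (-0.04 ± 0.13) were not called.

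The 88 calls became 315 with DESeq2 (115 higher and 200 lower), 45 with voom (30 and 15) and 107 with library totals (68 and 39). Leaving out a library gave between 43 (IgG IL-17 2) and 257 (IgG medium 1). All 5 scalings called 37 higher and 31 lower. Of the 32 called genes named here by the rule, 13 were called both in each scaling and with each library left out, Cxcl5, Cxcl1, Ccl2, Fas, Zc3h12a, Nfkbiz and Ccl7 among them.

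Transcripts changed by IL-17 in both RIPs, which share no library, numbered 34 higher (2.23 expected for independent sets of 863 and 46, one-sided Fisher exact p = 2.28e-35) and 4 lower (0.341 expected, Fisher exact p = 0.000369), with 0 called in opposite directions. Of these, 25 higher and 3 lower were called in both RIPs under all 5 scalings. The difference between the RIPs was called for Ccl7 and Vegfa (1.23, adjusted p = 0.0149) and not for the other 36. Among the latter were Cxcl5 (0.81, adjusted p = 0.563), Cxcl1 (0.47, adjusted p = 0.570) and Ccl2 (0.70, adjusted p = 0.151), as well as Zc3h12a (1.04, adjusted p = 0.148), Nfkbiz (0.46, adjusted p = 0.424) and Fas (0.82, adjusted p = 0.301). Neither of those calls remained with upper-quartile factors, library totals or factors from well-expressed genes, although the differences stayed above 0. They were 1.26 ± 0.23, 1.22 ± 0.24 and 1.18 ± 0.24 for Ccl7 (adjusted p from 0.0606 to 0.0777). For Vegfa they were 0.95 ± 0.22, 0.90 ± 0.22 and 0.86 ± 0.22 (adjusted p from 0.104 to 0.141).

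**Figure D3:**
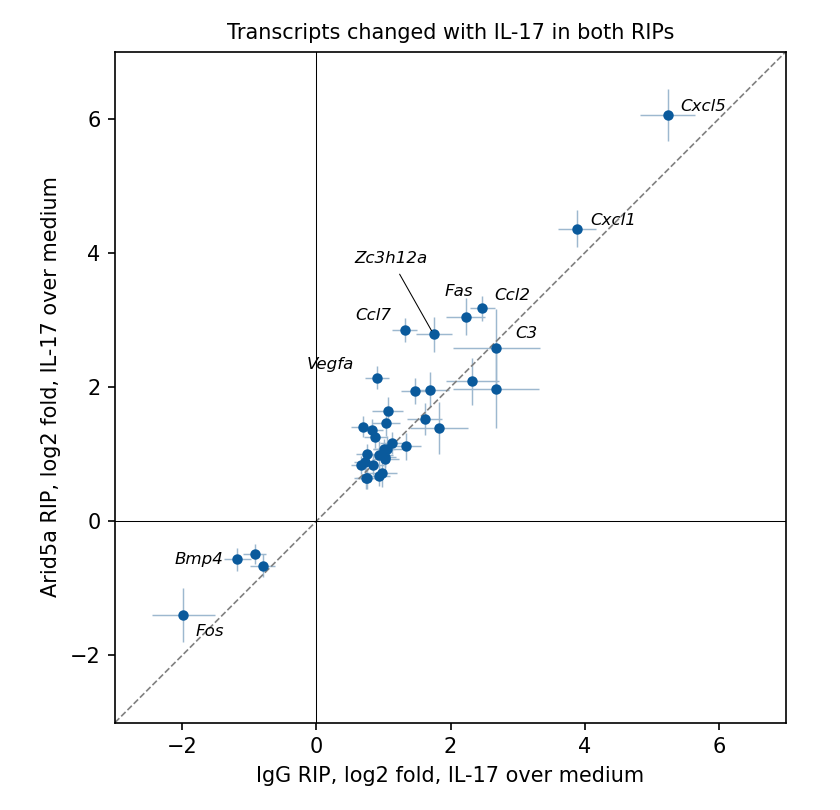
Log2 fold with IL-17 over medium in the IgG RIP (x axis) and in the Arid5a RIP (y axis) for the 38 transcripts called in both, with SE bars; the dashed line marks equal folds. Each point has the same sign in both RIPs, and 21 of the 34 higher transcripts lie above the line. With factors from well-expressed genes 13 would.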

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

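The tests with factors from well-expressed genes, with thinned Arid5a libraries, of the median folds of called transcripts and of the excess of calls in 1 direction were chosen after the results were seen.

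Many transcripts were higher with IL-17 in the Arid5a RIP (863 of 1008 calls). A difference in depth was argued against, since 753 calls were left after every Arid5a library was thinned to the total of the shallowest. Chance was argued against, since 1 of the 35 splits of the 8 Arid5a libraries, the real one, gave as many as 1008 calls. The highest of the others gave 0. The real split alone, 1 of 35, gave as large an excess of higher over lower calls (718). That is the smallest share this test can give. Every other split mixed IL-17 and medium libraries within its groups, which could widen their spread and lower their calls. Replicate 4 of Arid5a IL-17 stood apart from its group in receptor-gene CPM (4149, others 1269 to 1581). No split set it against the rest of its group alone, so the splits do not weigh this structure. A different share of counts on silent genes acting through the scaling stays open as a source of these calls, since 324 were left with factors from well-expressed genes, 113 of them higher. The median fold of the 863 transcripts moved from 0.66 (quartiles 0.56 and 0.80) to 0.34 (0.25 and 0.49) as the shared shift of 0.31 was removed. All 863 stayed above 0, 566 of them by more than 2 SE, so whether the scaling is the whole source of the folds cannot be told. A response of the cells to IL-17 stays open beside it, and Cxcl5, Cxcl1, Ccl2, Fas and Zc3h12a were called under all 5 scalings.

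Most of the transcripts called in medium were lower in the Arid5a RIP (102 of 112). Chance stays open, since 2 of the 35 splits of the 8 medium libraries gave as large a difference between the directions, 92 in the real one and 94 in another. The count of calls decides nothing, since it ignores the direction: 1 split, the real one, gave as many as 112, and the highest of the others gave 100. The scaling stays open as the source of the excess of lower calls, since 3 lower and 7 higher calls were left with factors from well-expressed genes. Whether it is the whole source of the folds cannot be told, since the 102 transcripts were chosen for low folds in the same fit. Their median moved from -0.78 (quartiles -0.89 and -0.69) to -0.59 (-0.70 and -0.49), by about the shared shift of -0.19 that the rescaling removed. For the sparse library IgG medium 2, the 2 lower calls left without it decide nothing, since 0 were left without IgG medium 3, Arid5a medium 2 or Arid5a medium 3. Without that library the median of the 102 transcripts was -0.65 (-0.80 and -0.57), so their low values did not rest on it alone. They were chosen with the other medium libraries in the fit, so this does not weigh that library as a source. A real difference in what the 2 antibodies bring down stays open as the biological reading, and it was not tested.

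Ccl7 rose more with IL-17 in the Arid5a than in the IgG RIP. With factors from well-expressed genes the difference moved from 1.53 ± 0.26 (adjusted p = 0.0148) to 1.18 ± 0.24 (adjusted p = 0.0777), and the call ended. The rescaling removed the shift of 0.35 shared by well-expressed genes, and 0 transcripts were called for this difference with these factors. The rescaled difference was still more than 2 SE above 0. This does not weigh the scaling, since Ccl7 was picked as a called gene and removing 0.35 could hardly bring 1.53 near 0. With each library left out the difference was also more than 2 SE above 0, the lowest being 1.42 ± 0.25 (adjusted p = 0.0102, without IgG medium 2). No single library made up the whole difference, although Ccl7 was picked with all of them in the fit. The call ended without Arid5a IL-17 1, at 1.49 ± 0.28 (adjusted p = 0.0621), where no transcript was called for this difference. Binding of Ccl7 mRNA to Arid5a after IL-17 may contribute as a hypothesis, which a RIP with total RNA from the same lysates and with cells lacking Arid5a would test. With IL-17, edgeR did not call Ccl7 higher in the Arid5a than in the IgG RIP (239.9 ± 33.14 against 159.9 ± 13.68 CPM). In medium edgeR called its level lower in the Arid5a than in the IgG RIP (33.25 ± 2.113 against 65.56 ± 18.77 CPM). This gap in medium makes up more of the difference of 1.53 than the gap with IL-17.

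Of 355 groups of 4 libraries, 20 had 1 library far from the others by Dixon's ratio, where chance alone gives about 1 in 20 groups, or 17.8. In IgG medium these were Il6 (ratio 0.885; replicate 4 at 1.92 CPM, others 0 to 0.221), Fstl3 (0.970; replicate 2 at 71.9, others 31.8 to 33.0), Gm32687 (0.948; replicate 3 at 10.5, others 4.49 to 4.80), Ddn (0.909; replicate 4 at 17, others 8.99 to 9.71), Tnc (0.906; replicate 2 at 202, others 129 to 136) and Rpl26 (0.902; replicate 2 at 635, others 751 to 764). In Arid5a medium they were Lcn2 (1; replicate 4 at 1.81, others 0), Zfp433 (1; replicate 2 at 0.826, others 0), Mfsd14a (0.866; replicate 2 at 24.0, others 25.4 to 25.6), Ccl2 (0.930; replicate 2 at 31, others 41.0 to 41.7), Nfkbia (0.867; replicate 2 at 15.7, others 29.2 to 31.3) and Pabpc1 (0.871; replicate 2 at 1329, others 1383 to 1391).

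In Arid5a IL-17, replicate 4 lay apart in receptor-gene CPM (ratio 0.892; 4149, others 1269 to 1581), Kcnj3 (0.878; 14.7, others 3.15 to 4.56), Scarna13 (0.849; 578, others 163 to 226), Celf1 (0.864; 120.0, others 179 to 189), Gpr101 (0.874; 5.10, others 1.68 to 2.11) and Meg3 (0.908; 42.8, others 15.3 to 17.8). Fas stood out through replicate 2 (0.902; 78.8, others 61.4 to 63.1) and Nfkbia through replicate 1 (0.916; 119, others 90.4 to 92.7).

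The effect of IL-17 differed between the RIPs, by the interaction test, for 38 of the genes named. The differences (log2, Arid5a minus IgG) were 8.63 for Gm32687, 2.65 for Alg8 (1.09 in the Arid5a and -1.56 in the IgG RIP), 2.23 for Zmynd19 (1.17 and -1.06), 1.89 for Cenpm (0.21 and -1.68), 1.76 for Rpn1 (1.08 and -0.68), 1.67 for Psmg4, 1.67 for Pdrg1, 1.64 for Pithd1, 1.63 for Mfsd14a, 1.61 for Prr13, 1.56 for Ostc, 1.53 for Ccl7 and 1.41 for Ap3s1. The fitted 8.63 of Gm32687, which is at 0 in IgG IL-17, is no bound. Next came Trip4 (1.38), Ppp1r11 (1.38), Vegfa (1.23), Cdk7 (1.20), Rpl35 (1.20), Psmd6 (1.19), Birc5 (1.15), Ywhaz (1.11), Ccl9 (1.11), Hprt (1.07), Rwdd1 (1.06), Ppia (1.06), Tacc3 (1.04), Esd (0.99), Psmd1 (0.93), Zfp36l2 (0.90), Malat1 (0.86), Neat1 (0.77) and Hsp90aa1 (0.62). Negative differences were those of Meg3 (-1.60), Cdh4 (-2.30), Ugt1a1 (-2.31), Pcdhga9 (-2.94), Gpr101 (-3.57) and Olfr1385 (-3.79). Of these, Vegfa, Ap3s1, Trip4, Ppp1r11, Cdk7 and Rwdd1 were named by the rule in another comparison, and Tacc3 and Esd were chosen after their values were seen.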

How the results depend on the processing

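Factors from well-expressed genes, the receptor covariate, the 2 joint removals and thinning were chosen after the data were seen; where a count moved, the cause was not tested unless stated.

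Counts are given for Arid5a against IgG in medium (112), with IL-17 (12), the difference (174), IL-17 in the Arid5a RIP (1008), IL-17 in the IgG RIP (88) and the overlap (1), where they moved by more than 1.5 times. Upper-quartile factors gave 4, 6, 0 and 321 for the first 4. Library totals gave 13 in medium, 0 for the difference and 301 in the Arid5a RIP. DESeq2 gave 327, 60 and 394, 315 in the IgG RIP and an overlap of 4, and voom gave 571, 1758, 7497 and 45 for the counts after medium. Testing without a filter gave 26 with IL-17, and the stricter filter, which tests fewer genes, 74 and 7. Only the libraries compared gave 1 in medium, 2977 and 16 for IL-17 in the Arid5a and IgG RIPs, and an overlap of 0. Limma gave 1, 5, 6, 113 and 45 on log2(FPKM + 1) and 1, 5, 2, 75 and 40 on log2(FPKM + 0.1).

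Factors from well-expressed genes gave 10, 0, 0 and 324 and an overlap of 0. The receptor covariate gave 0, 1, 0 and 27 and an overlap of 0 (767 and 894 at an unadjusted p below 0.05 by edgeR in medium and for the difference). Without IgG medium 2 and IgG IL-17 4 there were 15 calls in medium, 309 for the difference, 2600 in the Arid5a RIP and an overlap of 0. Without Arid5a IL-17 1, 2 and 3 together there were 28, 2, 0 (760 at an unadjusted p below 0.05), 12 and 52 and an overlap of 2; the lone Arid5a IL-17 library was assumed to vary like the other groups.

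Leaving out each library in turn gave 0 to 350 calls in medium, 2 to 76 with IL-17, 0 to 715 for the difference, 308 to 2257 in the Arid5a RIP, 43 to 257 in the IgG RIP and overlaps of 0 to 2. In medium, the count was 350 without IgG medium 1, 2 without IgG medium 2, 0 without IgG medium 3, Arid5a medium 2 or Arid5a medium 3, 65 and 5 without Arid5a medium 1 and 4, 61 without IgG IL-17 2, and 60, 59 and 51 without Arid5a IL-17 1, 2 and 3. With IL-17 it was 19 and 28 without IgG medium 1 and 2, 7 without Arid5a medium 2 or 4, 5, 33 and 2 without IgG IL-17 2, 3 and 4, and 3, 5 and 76 without Arid5a IL-17 1, 2 and 4. The difference had 443 and 9 without IgG medium 1 and 3, 20, 4 and 92 without Arid5a medium 2, 3 and 4, 5 and 64 without IgG IL-17 2 and 4, and 0, 5, 72 and 715 without Arid5a IL-17 1, 2, 3 and 4. In the Arid5a RIP there were 1822 without IgG medium 2, 533, 473, 447 and 600 without Arid5a medium 1 to 4, and 335, 308, 486 and 2257 without Arid5a IL-17 1 to 4. In the IgG RIP there were 257 and 47 without IgG medium 1 and 3, and 43, 55 and 50 without IgG IL-17 2, 3 and 4. The overlap was 0 without IgG medium 2, 3 or 4 or any 1 of the Arid5a medium libraries, and 2 without Arid5a IL-17 4.

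With the replicate number as a block there were 49 calls in medium, 5 with IL-17 and 85 for the difference. Of 21 pairs of libraries with the same number, 2 correlated above 0.1 in their residuals (r from -0.218 to 0.203, mean -0.0248 against 0.00729 for different numbers), and 3 of 15 libraries correlated best with their own number.

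Of the named genes called, 31 of 67 in the Arid5a RIP and 13 of 32 in the IgG RIP with IL-17 were called in every scaling and with each library left out, against 0 of 26 in medium, 0 of 12 with IL-17 and 0 of 33 for the difference. Without Arid5a IL-17 1, 2 and 3 the rise of Actg1 and Actb in the Arid5a RIP turned to -0.0540 and -0.00303. With library totals, ribosomal protein mRNAs in medium shifted higher (adjusted p = 0.0319, and 0.395 with an estimated correlation) instead of lower (adjusted p = 0.0691, and 0.603, not called). The alternative without mitochondrially encoded RNAs was void, as none are in the table. Depth limits low transcripts, with 0 counts in the shallowest library allowing up to 3.19 CPM.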

Other observations

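The tests of other splits below were planned, while the genes named in the last paragraph were chosen after their values were seen.

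For Arid5a against IgG with IL-17, chance cannot be excluded for the count of 12, since 2 of the 35 splits of the 7 libraries gave as many. The other split gave 86, setting Arid5a IL-17 1, 2 and 3 apart from the rest, and points to a structure of the samples. For IL-17 in the IgG RIP the same holds for the count of 88: 2 of 35 splits gave as many, and the highest other, 255, set IgG medium 2, 3 and 4 apart from IgG medium 1 and the IL-17 libraries. For the difference between conditions chance is argued against under TMM factors. There 1 of 60 drawn relabellings, the real one with 174 calls, gave as many, and the highest other gave 5. The other relabellings mixed Arid5a and IgG libraries within groups, which could widen their spread and lower their calls. The real grouping also carried the shift of 0.35 that TMM left over well-expressed genes, so the relabelling does not weigh the scaling. Relabelling was not run with upper-quartile factors, library totals or factors from well-expressed genes, each of which gave 0 calls in the real grouping.

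Among transcripts called with IL-17 in both RIPs, Il1rl1, the receptor of IL-33, rose by 1.64 ± 0.21 in the Arid5a RIP and 1.06 ± 0.22 in the IgG RIP, and Plk2 by 1.47 and 1.04. Fgfr1 rose by 1.08 and 1.06, Pmepa1 by 1.16 and 1.13 and Cd44 by 0.64 and 0.74. These were called in both RIPs under all 5 scalings, except Cd44, which was so under 2. The aggrecanase gene Adamts5 fell (-0.49 and -0.92) and was called in both under all 5.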
